A study of Mus musculus with 6 samples.

How the data were processed

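The 6 RNA-seq libraries compared came from mice on a high-fat diet for 26 weeks, 3 wild type and 3 with ARRB1 knocked out. The labels give C57BL/6 as the strain, liver as the source and hepatocytes as the cell type. The group of each library was taken from its title. The genotype labels of knockout replicates 2 and 3 name ARRB2 and ARRB3 and so differ from their titles and from the series text, which name ARRB1. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from 1 ug of total RNA with an Illumina TruSeq kit. Whether the libraries kept strand was not given in the sources used here, so a gene and an antisense partner could not be told apart.

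The values are FPKM (fragments scaled to the length of the gene and to the fragments of the library) as deposited by the authors, 1 value per gene and library for 46095 gene symbols. Per the submitters' processing notes, Bowtie 0.12.2 and HISAT2 were used, with the builds mm8 and mm10. The role of each tool and build, the HISAT2 version, the gene annotation and the treatment of reads that match several genes were not given in the sources used here. Values of gene families with near-identical copies (the Mup, Cyp2, Cyp3a, Cyp4a, Serpina1, Gst and globin genes) are therefore uncertain. Gene positions come from the GENCODE vM21 annotation of GRCm38, which corresponds to mm10, matched by symbol for 33912 symbols. The positions are not part of the deposited values. The mitochondrial genes of the lists were matched by identical coordinates.

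Depth was estimated from the FPKM steps. In a library, the FPKM of a gene is a whole multiple of the value of 1 read. Of the 17549 genes above 0 in at least 4 libraries, 17549 gave whole reads in all libraries, within 0.001 reads plus 5e-08 of the count and never more than 0.05 reads. With wrong steps, 0.3% of 2000 genes came out whole. On simulated reads, 98.34% of 9531 genes were returned exactly. Both checks used a search that stopped at lower counts than the search on the data. The latter went up to 2000000 reads in the library with the fewest. At such counts the tolerance is wide, so whole reads of the highest genes were not checked. The totals were set from the lengths of genes with 1 annotated transcript, of which 319 of 1756 fell in the most common 0.5% interval, so the totals are estimates. Relative depth between libraries does not depend on those lengths.

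Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend, two-sided) on log2(FPKM + 1), with genotype as the only term, for the 10633 genes with a mean of at least 1 FPKM over the libraries. P-values were adjusted by the Benjamini-Hochberg method over these genes, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, knockout minus wild type, and understate the change of low genes. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the 41 of 46 lists with at least 3 tested genes. A count adjusted over the list alone uses only the genes of that list. The labels do not say what a replicate is beyond the triplicate design, so p-values measure the spread between these libraries. With 3 against 3 libraries, an exact permutation test cannot go below 0.1.

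The design, gene lists and alternatives were fixed before the data were examined, apart from limma's voom on the recovered reads. The genes named are Arrb1, Arrb2, Arr3 and Gdf15, the 10 called genes per direction with the largest fold change and non-overlapping groups, and up to 4 members with the smallest p from each list described. Other genes named were chosen after their values were seen, and this is stated where they appear. Some genes that this rule names, and counts that rest on them alone, are not reported here. The alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, rescaling to TPM, median-of-ratios scaling, quantile normalization, eBayes without trend or with robust estimation, array weights, the replicate number as a block, each library left out, a 2-fold minimum, camera with an estimated correlation, and fry.

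The fit was tested on simulated reads for the knockout against wild-type comparison, with 200 genes changed by 2-fold or 4-fold and library depths as estimated. When each gene kept its own spread between libraries, 61.9% of the genes changed by 2-fold and 94.8% of those changed by 4-fold were recovered among 10599 tested genes, and 6 of the 157 calls were unchanged genes. With 1 spread shared by all genes, 100% of both sizes were recovered among 10621 tested genes, and 15 of 210 calls were unchanged genes. The first setting is nearer to the data, in which spread differed between genes. Intervals on shares of reads are exact Clopper-Pearson intervals at 95% and cover counting error only. Tests outside R used Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.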

Results

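Gene expression was measured by RNA-seq in liver material labelled as hepatocytes from mice fed a high-fat diet for 26 weeks, with 3 wild-type and 3 ARRB1 knockout libraries. ARRB1 is beta-arrestin 1, an adaptor of G protein-coupled receptors, and the study asked how its loss acts on diet-induced fatty liver disease and on GDF15, a secreted stress protein. The estimated depth was 33320000, 27910000 and 30310000 fragments in wild-type replicates 1 to 3 and 13910000, 35060000 and 29170000 in the knockout replicates. Knockout replicate 1 was thus the shallowest library, with 16975 genes above 0 FPKM against 18212 to 19124 in the other libraries. Correlations of log2 values lay between 0.9825 and 0.9876 within groups and between 0.957 and 0.9785 across them.

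The targeted gene, Arrb1 (chromosome 7, 99535466 to 99606771, plus strand, GRCm38), was low in each library labelled knockout. Its level was 0.918, 1.05 and 1.16 FPKM in the knockout replicates and 3.86, 22.7 and 16.9 FPKM in the wild-type replicates. The means were 1.04 ± 0.121 FPKM (SD, n = 3) and 14.5 ± 9.63 FPKM (SD, n = 3), a log2 fold change of -2.64 ± 0.514 (SE; limma, adjusted p = 0.0275), with no overlap between groups. The exact two-sided permutation p was 0.1, the smallest this design allows. Arrb2 (chromosome 11, 70432635 to 70440828) was at 0.362, 0.717 and 0.552 FPKM in the knockout replicates and at 0.272, 0.613 and 0.431 FPKM in wild type, below the filter. Arr3 (chromosome X, 100605497 to 100618493) was listed at 0 in each of the 6 libraries. The genotype labels of knockout replicates 2 and 3 name ARRB2 and ARRB3. Arr3 was also at 0 in wild type and Arrb2 rested on 5 to 25 reads per library, so neither level could check those labels. Arrb1 was low in both libraries. The call for Arrb1 was lost without wild-type replicate 2 (adjusted p = 0.0916) or 3 (0.07005), and without knockout replicate 1 (0.0596), 2 (0.1001) or 3 (0.0669).

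Gdf15 (chromosome 8, 70629393 to 70632456, minus strand) was not called. It measured 23.6, 108 and 71.7 FPKM in wild type and 32.3, 52.9 and 60.2 FPKM in knockout, a log2 fold change of -0.28 ± 0.505 (SE; limma, adjusted p = 0.771; exact permutation p = 0.8). Its sign turned without wild-type replicate 2, to 0.18. Among the 8 tested genes of the list of GDF15 and the proprotein convertases, which cleave secreted precursors, Pcsk6 rose from 35.5 ± 2.90 to 61.6 ± 3.75 FPKM (SD, n = 3 each). Furin was at 75.0 ± 4.29 FPKM in wild type and 90.8 ± 6.45 FPKM in knockout and was not called (limma, adjusted p = 0.115). The list as a whole did not pass by camera (adjusted p = 0.602) but did by fry (adjusted p = 0.0357), an alternative test. Adjusted over the list alone, 3 genes were higher.

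Across the transcriptome, 564 genes were higher and 170 were lower in the knockout libraries, of 10633 tested. At least 2-fold changes were found for 120 of the higher and 67 of the lower genes. The largest rises were those of Cyp2b9, a female-biased cytochrome P450 (1.12 ± 1.19 to 76.9 ± 34.1 FPKM, SD, n = 3 each), and of the lipid droplet protein gene Cidec (1.27 ± 0.800 to 53.1 ± 22.6 FPKM). Ly6d, Hbb-b1, Cidea, Cyp4a14, Anxa2, Cd36, Apoa4 and Wfdc2 followed, with log2 fold changes from 3.90 for Ly6d to 2.26 for Wfdc2. The largest falls were those of Hsd3b5, a male-biased steroid dehydrogenase (158 ± 35.5 to 6.72 ± 5.60 FPKM), Serpina1e (5509 ± 1342 to 280 ± 225 FPKM) and Mup7. Sqle, Tff3, Mup14, Mup11, Idi1, Enho and Msmo1 followed, with log2 fold changes from -3.27 for Sqle to -2.80 for Msmo1. Enho, which encodes the peptide adropin, went from 40.6 ± 5.12 to 4.92 ± 1.43 FPKM (limma, adjusted p = 0.00107). Both counts shrank when single libraries were left out, to 94 higher and 63 lower without knockout replicate 2, 117 and 54 without wild-type replicate 2, 242 and 92 without wild-type replicate 1, 329 and 115 without wild-type replicate 3, 422 and 112 without knockout replicate 1, and 256 and 119 without knockout replicate 3. The split depended on scaling: 76.8% of calls were higher as deposited, 59.9% after median-of-ratios scaling and 64.5% after quantile normalization, and 85.2% on the TPM scale.

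**Figure D1:**
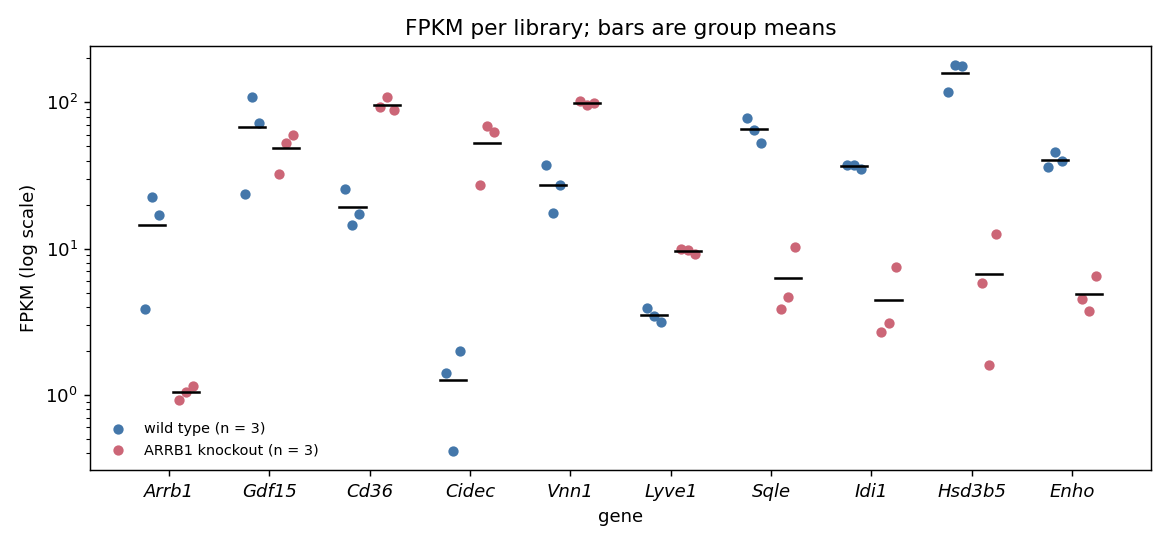
FPKM of 10 genes on a log axis, with 1 point per library (3 wild type and 3 knockout per gene) and a bar at each group mean. Arrb1 lay between 0.918 and 1.16 FPKM in the knockout libraries and between 3.86 and 22.7 FPKM in wild type, while the groups overlapped for Gdf15.

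Genes of cholesterol synthesis fell together. Of the 24 tested, 22 were lower and none was higher, with a median log2 fold change of -1.92 (camera, adjusted p = 2.326e-37, and adjusted p = 0.456 with an estimated correlation). Adjusted over the list alone, 23 were lower. Sqle, the squalene epoxidase gene (chromosome 15, from 59315077), went from 65.3 ± 13.1 to 6.28 ± 3.52 FPKM (SD, n = 3 each), and Idi1 went from 36.6 ± 1.46 to 4.43 ± 2.67 FPKM. Pmvk had the smallest adjusted p of all genes, with 46.6 ± 1.06 FPKM in wild type and 12.01 ± 0.707 FPKM in knockout (limma, adjusted p = 0.000204). Fdft1 and Tm7sf2 fell by 2.20 and 1.42 on the log2 scale. Between 18 and 22 members were called with any 1 library left out.

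Fatty acid oxidation genes, including targets of the nuclear receptor PPAR-alpha, were higher for 17 of 28 tested and lower for none (median log2 fold change 0.61; camera, adjusted p = 1.281e-09, and adjusted p = 0.456 with an estimated correlation). Adjusted over the list alone, 22 were higher. Vnn1 rose from 27.3 ± 9.71 to 98.6 ± 3.25 FPKM (SD, n = 3 each), Acadm from 157 ± 14.5 to 253 ± 22.2 FPKM, and Pex11a from 26.9 ± 5.66 to 59.6 ± 11.3 FPKM. Genes of lipid droplets and PPAR-gamma targets were higher for 8 of 16 tested, and 12 when adjusted over the list alone (median 0.99; camera, adjusted p = 1.887e-08, and adjusted p = 0.456 with an estimated correlation). The fatty acid transporter gene Cd36 rose from 19.1 ± 5.81 to 96.6 ± 10.3 FPKM, Mogat1 from 0.517 ± 0.288 to 5.31 ± 0.314 FPKM, and Fitm2 from 20.6 ± 2.71 to 39.3 ± 3.59 FPKM. The fatty acid oxidation count dropped to 3 without wild-type replicate 2, 7 without knockout replicate 3 and 2 without knockout replicate 2, and to 11 without wild-type replicate 1 or knockout replicate 1. The lipid droplet count was 5 without knockout replicate 2. Fatty acid and triglyceride synthesis genes moved in both directions, 2 higher (Thrsp, Me1) and 2 lower (Acss2, Acly) of 22 (camera, adjusted p = 0.782), and 5 higher and 3 lower when adjusted over the list alone. The 2 higher calls were lost without wild-type replicate 2 or 3 or knockout replicate 2, and 1 lower call without wild-type replicate 2 or knockout replicate 2.

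Genes expressed more in male than in female mouse liver were lower for 11 of 16 tested, and for 13 when adjusted over the list alone (median log2 fold change -1.97; camera, adjusted p = 9.605e-17, and adjusted p = 0.456 with an estimated correlation). Mup21 went from 92.5 ± 19.9 to 18.02 ± 2.49 FPKM and Susd4 from 17.7 ± 6.00 to 4.73 ± 1.09 FPKM (SD, n = 3 each). Of 6 tested female-biased genes, 3 were higher, also when adjusted over the list alone (median 1.23; camera, adjusted p = 0.001489, and adjusted p = 0.456 with an estimated correlation). These were Cyp2b9, Cyp2b13 and Cyp2a4, members of P450 families with close copies. All 3 lie between 26061497 and 26315088 on chromosome 7, the chromosome of Arrb1, so they do not stand for 3 separate loci. The other 9 of the 15 female-biased liver genes listed were below the filter, which Cyp2b13 (0.010 FPKM in wild type) and Cyp2a4 (0.108 FPKM) passed through their knockout values of 3.81 and 2.89 FPKM. With no filter the female-biased median was 0.23 (camera, adjusted p = 0.0131), and Cyp2b13 (adjusted p = 0.0946) and Cyp2a4 (adjusted p = 0.107) lost their calls. The female-biased median was 0.43 without knockout replicate 1 and 0.68 without knockout replicate 2. The female-biased count was 1 without any of the wild-type replicates or knockout replicate 2, and 5 without knockout replicate 3. The male-biased count was 5 without wild-type replicate 1 or 3 or knockout replicate 1, and 4 without wild-type replicate 2 or knockout replicate 2.

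Extracellular matrix genes were higher for 11 of 27 tested, and for 16 when adjusted over the list alone (median log2 fold change 0.56; camera, adjusted p = 1.752e-07, and adjusted p = 0.471 with an estimated correlation). Col3a1, a fibrillar collagen gene, rose from 10.1 ± 1.27 to 26.8 ± 9.75 FPKM, Postn from 1.89 ± 0.212 to 4.62 ± 0.645 FPKM, and Ctgf from 4.44 ± 0.521 to 10.1 ± 1.59 FPKM (SD, n = 3 each). Markers of monocyte-derived and lipid-associated macrophages were higher for 4 of 9 tested, and for 8 when adjusted over the list alone (median 0.94; camera, adjusted p = 0.0001767, and adjusted p = 0.471 with an estimated correlation). Gpnmb was at 2.42, 9.66 and 3.40 FPKM in the knockout replicates and 0.154 ± 0.0244 FPKM in wild type. Lgals3 rose from 5.53 ± 1.05 to 16.4 ± 6.51 FPKM, and Mmp12 from 0.140 ± 0.115 to 3.18 ± 1.69 FPKM. Gpnmb and Mmp12 passed the filter only through their knockout values, and 9 of the 13 listed macrophage markers passed it. Markers of stellate cells (median 0.11; camera, adjusted p = 0.976) and of Kupffer cells (median 0.16, adjusted p = 0.887) did not pass as lists, nor did endothelial (median 0.18, adjusted p = 0.154) or cholangiocyte markers (median 0.26, adjusted p = 0.711). Limma called 0 of 12 stellate markers, 1 of 15 Kupffer cell markers (lower), 2 of 13 endothelial and 1 of 8 cholangiocyte markers (higher). Adjusted over the list alone, 3 Kupffer cell markers were higher and 1 lower, and 4 endothelial and 1 cholangiocyte markers were higher. The calls numbered 0 or 1 for Kupffer cells and cholangiocytes and 1 or 2 for endothelium with 1 library left out. With 1 library left out, the medians ran from 0.0067 (without knockout replicate 2) to 0.23 (without knockout replicate 3) for stellate cells and from -0.0091 (without wild-type replicate 3) to 0.36 (without knockout replicate 1) for Kupffer cells. They ran from -0.053 (without knockout replicate 2) to 0.40 (without wild-type replicate 3) for cholangiocytes. The endothelial list passed without wild-type replicate 3 (adjusted p = 0.04554). The matrix count was 3 without wild-type replicate 1 or 2, 4 without wild-type replicate 3 and 6 without knockout replicate 2 or 3. The macrophage count was 1 without wild-type replicate 1, 0 without wild-type replicate 2, and 2 without knockout replicate 2 or 3.

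**Figure D2:**
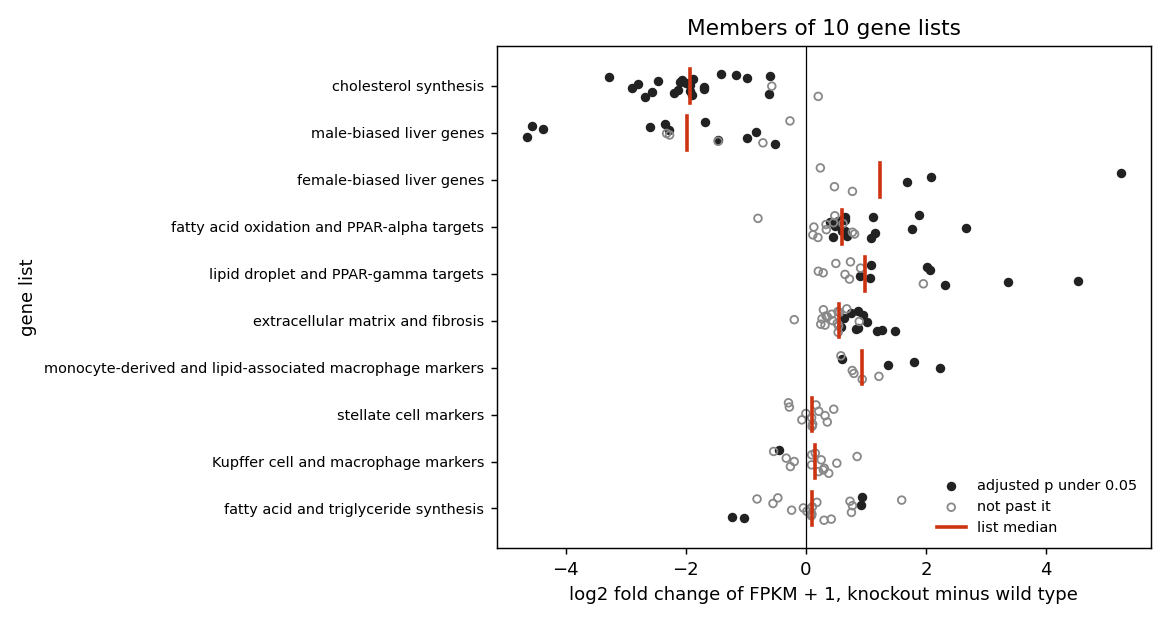
Log2 fold changes of FPKM + 1 (knockout minus wild type) for the tested members of 10 gene lists, with filled points past adjusted p 0.05, open points not past it, and a vertical bar at each list median. The medians were -1.92 for cholesterol synthesis, 0.99 for lipid droplet genes and 0.11 for stellate cell markers.

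Hepatocyte markers were lower for 2 of 17 tested, and 3 when adjusted over the list alone, with a small shift (median log2 fold change -0.14; camera, adjusted p = 0.0003046, and adjusted p = 0.456 with an estimated correlation). Amino acid and urea genes were lower for 4 of 20, and 7 when adjusted over the list alone (median -0.28; camera, adjusted p = 1.204e-07, and adjusted p = 0.456 with an estimated correlation). Cps1, the first enzyme of the urea cycle, fell from 308 ± 22.9 to 180 ± 13.0 FPKM and Gnmt from 1046 ± 99.2 to 670 ± 49.6 FPKM (SD, n = 3 each). Of 13 tested p53 targets, 5 were higher, among them Ccng1 and Phlda3 (median 0.51; camera, adjusted p = 0.009224, and adjusted p = 0.456 with an estimated correlation), and 10 were higher and 1 lower when adjusted over the list alone. Of 16 antioxidant genes, 3 were higher, among them Srxn1 and Nqo1 (median 0.25; camera, adjusted p = 0.009224, and adjusted p = 0.499 with an estimated correlation), and 8 when adjusted over the list alone. The hepatocyte marker count was 1 without wild-type replicate 2 or knockout replicate 2, the median ran from -0.21 without wild-type replicate 2 to -0.08 without wild-type replicate 3, and the list call was lost after quantile normalization. The amino acid count was 2 without wild-type replicate 1 or 3 or knockout replicate 3, and 1 without wild-type replicate 2 or knockout replicate 2. The p53 count was 3 without wild-type replicate 1 or 3, 1 without wild-type replicate 2 or knockout replicate 2, and 2 without knockout replicate 3, and the antioxidant count was 0 without wild-type replicate 2 or knockout replicate 2 and 1 without knockout replicate 3. The antioxidant list call was lost with the filter at 5 FPKM.

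In all, 19 of the 41 tested lists passed, and none did with an estimated correlation. Periportal hepatocyte genes had 3 lower members (Cps1, Etnppl and Hal) and 1 higher (Hsd17b13) of 12, and 5 lower and 1 higher when adjusted over the list alone (camera, adjusted p = 0.001277, and adjusted p = 0.456 with an estimated correlation). The lower count was 1 without wild-type replicate 1 or 3 or knockout replicate 2 or 3, and 2 without wild-type replicate 2 or knockout replicate 1, and the higher call was lost without knockout replicate 2. Bile acid genes went both ways, with Abcc3, Abcb4 and Slco1a4 higher and Cyp7b1, Fgfr4 and Slco1a1 lower of 22, and 3 higher and 4 lower when adjusted over the list alone (camera, adjusted p = 0.02146, and adjusted p = 0.456 with an estimated correlation). The lower bile acid calls numbered 0 without wild-type replicate 2 or knockout replicate 2 and 1 without wild-type replicate 1 or knockout replicate 1, and the higher calls 1 without wild-type replicate 1 or knockout replicate 2. Slco1a4 and Slco1a1 were named after their values were seen. Of 22 acute phase genes, Orm3 was higher and Itih3 lower, also when adjusted over the list alone (camera, adjusted p = 0.003443, and adjusted p = 0.617 with an estimated correlation). The acute phase list had no called gene without wild-type replicate 2 or knockout replicate 2, no lower one without knockout replicate 1 or 3, and 3 lower without wild-type replicate 3. Immediate early genes had 0 of 15 called by limma or by voom, and 0 of 15 at an unadjusted p under 0.05 (camera, adjusted p = 0.04306, and adjusted p = 0.748 with an estimated correlation). Egr1 was at 11.6, 180 and 203 FPKM in wild-type replicates 1 to 3 and at 2.67, 21.2 and 89.9 FPKM in the knockout replicates. The bile acid and acute phase list calls were lost after median-of-ratios scaling and quantile normalization, and also without wild-type replicate 2 (adjusted p = 0.2556 and 0.1179) or knockout replicate 2 (0.09483 and 0.1369). The bile acid call was also lost with no filter. Without wild-type replicate 1, 1 immediate early gene was lower. The list's median of -0.45 turned to 0.11 without wild-type replicate 2 and 0.15 without knockout replicate 1, and was -0.88 without wild-type replicate 1. The immediate early call was lost with no filter, after both scalings, with array weights and with voom, chosen after seeing the data, and without wild-type replicate 2 (adjusted p = 0.4036) or 3 (0.08857) or knockout replicate 1 (0.4498) or 2 (0.1503).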

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

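The number of higher genes, 564 as reported, was 88 with no filter, 990 on the TPM scale, 346 after median-of-ratios scaling, 371 after quantile normalization and 120 with a 2-fold minimum. The number of lower genes, 170 as reported, was 58 with no filter and 67 with a 2-fold minimum. With no filter more genes entered the adjustment (22476), and a 2-fold minimum removes calls by construction. For the scalings, the number of higher genes followed the median log2 fold change of all tested genes. That median was 0.0746 as deposited and 0.131 on the TPM scale. It was -0.0122 after median-of-ratios scaling and -0.00608 after quantile normalization. Part of the excess of higher genes thus depends on the scaling, and which scaling is right was not tested. With 1 library left out, the higher genes ranged from 94 to 422 and the lower genes from 54 to 119, on fewer samples. The number of lists past the threshold, 19, was 9 by fry and 0 with an estimated correlation, and 15 to 22 with 1 library left out. The 9 included antigen presentation and the list of GDF15 and the proprotein convertases, which were not among the 19. The others were the cholesterol synthesis, fatty acid oxidation, lipid droplet, amino acid, p53, male-biased and female-biased lists. The Arrb1 log2 fold change stayed negative in all alternatives. Its call was lost with no filter (-2.64, adjusted p = 0.117) and with robust eBayes (-2.64, adjusted p = 0.0769), for which the cause was not tested, and it ranged from -3.33 to -2.19 with 1 library left out. With the replicate block, 280 genes were higher and 122 lower. The main fit was planned without that block, since the labels do not say what a replicate number stands for. Deviations of same-numbered libraries correlated at 0.17, -0.0625 and 0.0966, and so few libraries can neither show nor exclude pairing. Limma's voom on recovered reads, chosen after seeing the data, called 799 higher and 198 lower genes, of which 713 were among the 734 as reported. Some genes not called changed sign: Gdf15 (0.24 with array weights), H2-K1 (-0.019 after median-of-ratios scaling, -0.00045 after quantile normalization), B2m (-0.033 after median-of-ratios scaling), Jchain (0.10 with array weights, 0.12 with voom). With 1 library left out, Gdf15 ranged from -0.90 to 0.18, Scd2 from -0.014 to 0.24, Jchain from -0.36 to 0.29 and Hba-a1 from -1.41 to 0.038. Of 101 called genes among those tracked one by one, 66 lost the call with no filter, 56 of the 100 tested without knockout replicate 2 and 54 without wild-type replicate 2, and none reversed. Depth limits low genes most in knockout replicate 1, at 0.3966 of the deepest library.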

Other observations

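All tests of the 3 patterns weighed here were chosen after the results were seen. Other groups also differed. Of 15 tested circadian clock genes, Dbp and Nr1d1 were higher and Cry1 and Arntl lower. Adjusted over the list alone, 4 were higher and 4 lower. The list did not pass as a whole (camera, adjusted p = 0.684). Camera tests for a shift in 1 direction, so it cannot decide whether genes moving both ways differ as a set. None of Dbp, Nr1d1, Cry1 and Arntl was called without wild-type replicate 2 or knockout replicate 2. Arntl lost its call without any 1 of the 6 libraries, and Nr1d1 kept its call only without knockout replicate 3. The mitochondrially encoded genes were lower as a list (median log2 fold change -0.30; camera, adjusted p = 1.84e-05, and adjusted p = 0.456 with an estimated correlation), with 1 of 13 called, ND3, which went from 3.72 ± 0.367 to 0.850 ± 0.125 FPKM (SD, n = 3 each). ND3 rested on few reads, 48, 34 and 37 in wild type and 4, 9 and 10 in knockout. Ribosomal protein genes had a median of -0.20 with 0 of 33 called by limma or by voom and 3 at an unadjusted p under 0.05 in limma (camera, adjusted p = 1.204e-07, and adjusted p = 0.570 with an estimated correlation). Their median was -0.1095 without wild-type replicate 3 and -0.1124 without knockout replicate 1. Erythroid markers (median -0.91; camera, adjusted p = 0.01966, and adjusted p = 0.471 with an estimated correlation) and sex chromosome genes (median -0.26; camera, adjusted p = 0.02301, and adjusted p = 0.471 with an estimated correlation) each had 0 of 4 called by limma or by voom, with 2 and 0 at an unadjusted p under 0.05 in limma. The 2 were Hbb-bs (-1.77) and Hbb-bt (-1.25), whose haplotype had a smaller share of beta-globin reads in knockout, so the list is not read as a measure of blood. Hba-a1 (-0.56) and Alas2 (-0.26) were the others. The erythroid list had 2 lower genes and a median of -1.67 without knockout replicate 2, the median was -0.56 without knockout replicate 1, and the sex chromosome median -0.11 without wild-type replicate 2. The erythroid call was lost with the filter at 5 FPKM and after both scalings, median-of-ratios and quantile, and the sex chromosome call after median-of-ratios scaling. The erythroid call was also lost without wild-type replicate 2 (adjusted p = 0.05337) or knockout replicate 1 (0.05559) or 3 (0.06923), and the sex chromosome call without wild-type replicate 2 (0.1244) or knockout replicate 3 (0.06622). Lyve1, an endothelial marker, was at 3.53 ± 0.392 FPKM in wild type and 9.64 ± 0.361 FPKM in knockout. Nnt on another chromosome than Arrb1, named after its values were seen, was at 22.2, 62.4 and 38.4 FPKM in the knockout replicates and 15.1, 15.5 and 17.1 FPKM in wild type and was not called (limma, adjusted p = 0.0626).

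The real grouping gave 734 called genes, and the highest count among the other groupings was 0. As 3 against 3 libraries make 10 splits, of which 1 gave as many genes, a share under 0.05 could not be reached.

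Hbb-b1 and Hbb-b2 are the adult beta-globin genes of a haplotype other than the one C57BL/6 mice carry, which has Hbb-bs and Hbb-bt. They made up 86.7% (95% exact interval 79.7 to 91.9), 65.4% (63.0 to 67.6) and 75.8% (69.9 to 81.1) of adult beta-globin reads in the knockout libraries and 0.304%, 0.679% and 1.0% in wild type. More blood of the same haplotype would leave these percentages as they were, and is argued against as the cause for Hbb-b1, since the lowest knockout percentage of 65.4% had a lower bound of 63.0%, above the highest wild-type bound of 2.54%. The amount of blood itself was not settled, as Hba-a1 was at 7.85, 39.4 and 4.42 FPKM in the knockout replicates and 10.9, 25.1 and 19.1 FPKM in wild type. The beta-globin genes lie on chromosome 7, as does Arrb1, so these reads make DNA of another strain kept around Arrb1 a candidate explanation. How far such DNA reached, and whether it was confined to this region, was not tested. In the 10 Mb around both loci 9 of 75 tested genes were called, leaving out Arrb1 itself as the targeted gene. That percentage was above that of 89.4% of 141 other windows, short of the 95% set for it. The count cannot decide the question, since DNA of another strain need not change the expression of many nearby genes.

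Of the extracellular matrix and lipid-associated macrophage genes, 11 of 27 and 4 of 9 were higher in the knockout libraries, and both lists lost their call with an estimated correlation (adjusted p = 0.471 for each). Both also missed the threshold by fry (adjusted p = 0.0576 and 0.0777). A lower share of hepatocyte RNA would raise the markers of all other cell types alike. The mean log2 fold change of the 36 genes exceeded that of 48 markers of stellate, Kupffer, endothelial and bile duct cells by 0.5974 (SE 0.09494). This difference cannot decide the question, as both lists were picked after they had passed and the 48 markers came from lists that had not. Those markers had a mean of 0.1671 (SE 0.05394) and hepatocyte markers one of -0.1994 (SE 0.06983). A lower share may thus account for part of the rise. The median of all tested genes was itself 0.0746 as deposited and -0.0122 after median-of-ratios scaling, so scaling may add to the marker mean. How much each contributed was not settled. Knockout replicate 2 alone is argued against, since without it the median of the 36 genes was 0.5765, against 0.6605 with all libraries. The SE of the mean over these genes was then 0.06799. All SEs in this paragraph are over genes, which can move together, and do not measure spread between animals. A genotype effect may remain, and so may a difference in strain background. The same holds for how much disease each animal had and how the cells were prepared. None of these was tested. As each knockout library had mostly reads of the other beta-globin haplotype, strain background could not be told apart from loss of Arrb1 for any called gene.

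In the knockout libraries 11 of 16 male-biased genes were lower and 3 of 6 tested female-biased genes higher, with 9 more listed but below the filter. Both lists lost their call with an estimated correlation (camera, adjusted p = 0.456 for each) and passed by fry (adjusted p = 0.0357 and 0.0292). Female animals in the knockout group are argued against by Xist, whose highest level in a knockout library was 0 FPKM. The Y-linked genes also argue against it, with a median log2 fold change of -0.26 against -1.97 for the male-biased genes. Reads shared between neighbouring gene copies are argued against as the whole cause, since the 4 male-biased genes with no such copy (Susd4, Cyp7b1, Elovl3 and Moxd1) had a median of -1.567. The SE of their mean was 0.266, taken over genes, and leaves out spread between animals. Of these 4 genes, Moxd1 was not called, and the genes were chosen by position after their values were seen. The 3 higher female-biased genes lie close together on chromosome 7, the chromosome of Arrb1 and the beta-globin genes. Hormone levels and strain differences beyond the beta-globin locus were not analysed here and stay open.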
